A study of Mus musculus with 4 samples.

How the data were processed

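GATA2 occupancy was profiled by CUT&Tag, in which an antibody bound to chromatin directs a protein A fusion of the Tn5 transposase to cut and tag the DNA around it. The cells were germ cells of female mouse fetuses at embryonic day 13.5, purified from ovaries by the BVSC reporter (a Blimp1-mVenus and a Stella-ECFP transgene, named for the genes Prdm1 and Dppa3). The 4 samples fell into 2 groups. A GATA2 antibody was used in 2 libraries, and the other 2 were input libraries labelled as having no antibody. Groups and replicate numbers were taken from the sample titles.

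The data were 1 peak list for the series, and its peak names carry a word for a combined library, so the values were taken to be pooled over both GATA2 replicates. No value belonged to a single replicate, and the spread between replicates could not be measured. The list, with no header line, followed the narrowPeak layout. The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.3.5.1, SAMtools, Picard 2.23.0, MACS2 2.2.6 and bedtools 2.29.2, with the mouse build GRCm38 (mm10). The parameters, the role of each tool and the libraries that served as control are not given in the sources used here. The deposited fold enrichment is the caller's ratio of the signal at a summit to its local background, with 1 added to both. Since the background was mostly far below 1, the fold lies close to the scaled signal plus 1 and is far lower than the plain ratio of signal to background. The deposited −log10 p and −log10 q values are the caller's unadjusted and adjusted significance at the summit. The deposited display score equalled the whole part of 10 times −log10 p in all 995 entries, and the lowest −log10 p was 3.09. MACS2 writes that score when peaks are selected on p rather than q. All these values describe 1 peak each and were used to describe, rank or filter peaks within the list.

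Depth was not given. In MACS2 the p-value is the upper tail of a Poisson distribution at the whole part of the scaled pileup, and the fold is (pileup + 1) / (background + 1). Both were solved together for each summit. A scale of 0.378 for the GATA2 fragments, a genome-wide background of 0.0608 control fragments per position and whole fragment numbers gave back the fold and p of all 995 summits, with fragment numbers within 0.0000986 of a whole number (0.05 was allowed). The local backgrounds of 989 summits lay within 1% of the genome-wide level, or within 0.01 of a step of a whole number or of a multiple of 1 step, which corresponds to a fragment length of 203 bp. A scale other than 1 means that a separate control was used, and that the pooled GATA2 library was 2.65 times its size. The genome-wide averages were 3.00 control and 7.93 GATA2 fragments per 10 kb. These numbers are inferred from the deposited values. They cover counting error only, and PCR copies that were not removed would count as separate fragments. On simulated summits the same solution recovered the fragment number of 995 of 995. The simulated backgrounds stayed below the highest ones of the real list, at Prdm1, Dppa3 and a ribosomal RNA region. Recovery at summits with such backgrounds was not tested. Recovery was lower in an earlier simulation, with another scale, in which the scaled pileup often fell exactly on a whole number.

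Gene positions came from a RefSeq gene table of GRCm38.p6, the build the submitters' notes name, with 21900 protein-coding genes. All summits lay within the annotated span of their chromosome. The table gives each gene's start and end but no strand, exons or UTRs, and no genome sequence was used here. The planned distance to a transcription start site was therefore replaced by the distance to the nearest protein-coding gene boundary, either end, and "boundary" below has that meaning. The planned tests of the GATA recognition motif, of a motif panel and of 6-mers, and the backgrounds matched on GC content, were not run. Coordinates are 1-based.

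Summits were sorted into 4 classes by position and compared with 10 random positions per summit on the same chromosomes, by Fisher's exact test with Benjamini-Hochberg adjustment over the classes. The share at boundaries was also compared between weak and strong summits, which was not part of the plan fixed before the data were examined. For 14 gene lists, fixed before the data were examined, the number of member genes whose boundary was the nearest to a summit, within 100 kb, was compared with 10000 random summit sets. These were matched on chromosome and on distance to the boundary, in bins with edges at 1, 5, 50 and 500 kb. Two-sided permutation p-values were adjusted over the 14 lists. The lists cover pluripotency, germ cell, meiosis, oocyte, GATA family, signalling (BMP and TGF-beta, WNT, retinoic acid), chromatin repression, mitotic cell cycle and ribosomal protein genes, and markers of the somatic gonad, blood and endothelium as other cells a sort could hold. All 413 listed symbols were matched to the table, 4 of them through older names. On simulated summit sets without enrichment, drawn in the same way as the random sets, 1.07% of 1400 list tests had a p under 0.05. The test was conservative for sets drawn that way, which does not show that it is so for real summits. As a trial of power, 6 summits of each simulated set were moved to 6 members of the WNT list, within 1 kb of a boundary. The WNT list then passed in 83 of 100 simulated sets. Intervals of shares are 95% exact (Clopper-Pearson) binomial intervals. For lists with a count of 0, the upper limit given is instead the approximate rule of 3, which is 3 divided by the number of genes. That limit treats the listed genes as a random sample. It covers neither the sequencing depth nor the rule that gives a summit to its nearest gene only.

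Genes named in the text were chosen by a rule fixed before the data were examined. The rule takes the nearest gene of the 15 summits with the highest fold, up to 4 members of each list by fold, the 5 genes with the most summits, with ties kept, and 14 genes named whether or not they had a summit. List members beyond these 4 are named where a list's members are counted, after their values were seen. Alternatives tried were stricter peak thresholds, other distance limits, boundaries of all annotated genes, placement by overlap, Fisher's exact test over genes and, chosen after seeing the data, 1 summit per interval, a q of at most 0.05, removal of 3 doubtful loci and assignment of each summit to every gene within 100 kb. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.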

Results

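To locate the chromatin sites occupied by the transcription factor GATA2 in female fetal germ cells, CUT&Tag was performed with a GATA2 antibody on sorted germ cells at E13.5, the stage at which these cells leave the mitotic, pluripotency-expressing state and approach meiosis. The pooled list of 2 GATA2 libraries held 995 summits in 945 intervals, and 40 intervals held more than 1 summit. Intervals had a median width of 332 bp, with quartiles of 261 and 486 bp. The fold enrichment had a median of 4.15 and quartiles of 3.44 and 5.22. It reached 10 or more at 33 summits and stayed under 5 at 722 summits (72.6%). A q of at most 0.05 was reached by 674 summits (67.7%), and the other 321 (32.3%) passed on the unadjusted p alone. The peak caller's values corresponded to a median of 9 GATA2 fragments at the summit (quartiles 8 and 13), against 51 fragments at the summits with the highest fold. The 95% Poisson interval of a single count is 4.12 to 17.1 for 9 fragments and 38.0 to 67.1 for 51. Which libraries gave the control behind the background is not given in the sources used here, and no comparison of the 2 GATA2 with the 2 input libraries was possible. The list gives no replicate spread, so the tests below compare positions within the list with random positions.

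**Figure D1:**
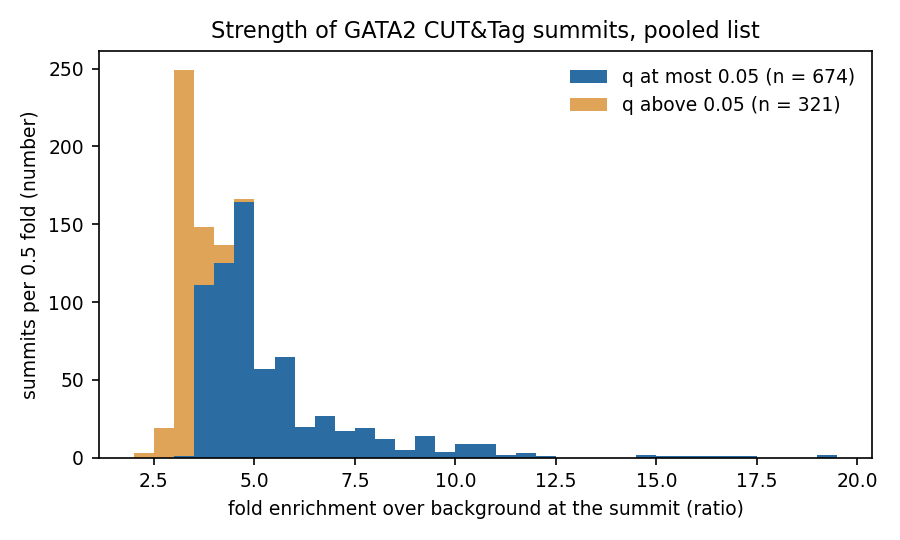
Number of GATA2 CUT&Tag summits (vertical axis, per bin of 0.5) by fold enrichment over background at the summit (horizontal axis, ratio). Blue marks the 674 summits with a q of at most 0.05 and orange the 321 summits above it, stacked. Most summits lie under a fold of 5, and 33 lie at 10 or more.

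The strongest summits lay both at gene ends and far from them. The highest fold, 19.1 (−log10 q 34.4), was shared by a summit inside Mnat1 and nearest to the homeobox gene Six4 (chromosome 12, 73118822 to 73119775, 5.1 kb from a Six4 boundary) and by a summit 71 bp outside a boundary of the zinc finger repressor gene Zbtb20 (chromosome 16, 42875056 to 42875893). A summit inside Prdm1, which encodes the germ cell determinant BLIMP1, followed at 17.5-fold (chromosome 10, 44468386 to 44469290). The next were Stk40, a kinase gene (16.6-fold, 109 bp from a boundary), and the neuronal kinesin gene Kif1a (16.3-fold, inside the gene, 32.8 kb from its nearer end). Tcf3, which encodes an E protein (15.9-fold, 28 bp), and Etv5, an ETS factor gene induced by FGF signalling (15.2-fold, inside the gene, 7.5 kb from its end), came after them. Auh (86.0 kb away) and the cholesterol transporter gene Npc2 (7 bp) both stood at 14.6-fold. The remaining 6 of the first 15 summits were nearest to Cs, encoding citrate synthase (12.3-fold), Dnah2 (12.0-fold), Porcn (12.0-fold), the serine synthesis gene Psat1 (11.6-fold), the mitochondrial carrier gene Slc25a23 (11.3-fold) and Id3 (11.3-fold). The annotation used does not give exons or strand, so introns, UTRs and the 2 ends of a gene could not be told apart. All 15 had a q far below 0.05, the weakest with a −log10 q of 13.9.

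Summits were concentrated at the ends of protein-coding genes. Of the 995 summits, 365 (36.7%, 95% exact interval 33.7% to 39.8%) lay within 1 kb of a boundary, against 3.26% of 9950 random positions, an 11.3-fold excess (Fisher's exact test, adjusted p = 2.49e-214). The zone from 1 to 5 kb held 15% of summits and 10.3% of random positions (Fisher's exact test, adjusted p = 1.26e-05). Positions inside genes and over 5 kb from any boundary held 23.6% of summits against 33.4% at random (exact test, adjusted p = 1.96e-10). Positions between genes and over 5 kb away held 24.7% against 53.1% (exact test, adjusted p = 2.94e-67). The share at boundaries was lower among the summits of highest fold than among those of lowest fold. It was 41.9% (35.7% to 48.3%) among the 248 summits of lowest fold and 29.3% (23.7% to 35.4%) among the 249 of highest fold (Fisher's exact test, two-sided p = 0.00369). In the groups between them, in order of rising fold, it was 42.2% and 33.3%. Summits with a q above 0.05 lay at boundaries more often (42.7%) than those with a q of at most 0.05 (33.8%; Fisher's exact test, p = 0.00751). The 995 summits were nearest to 861 different genes, of which 764 had 1 summit. With a window of 3 kb the excess at boundaries was 5.16-fold, and with the boundaries of all annotated genes 6.49-fold. Random positions were not matched on GC content or on how well reads map.

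**Figure D2:**
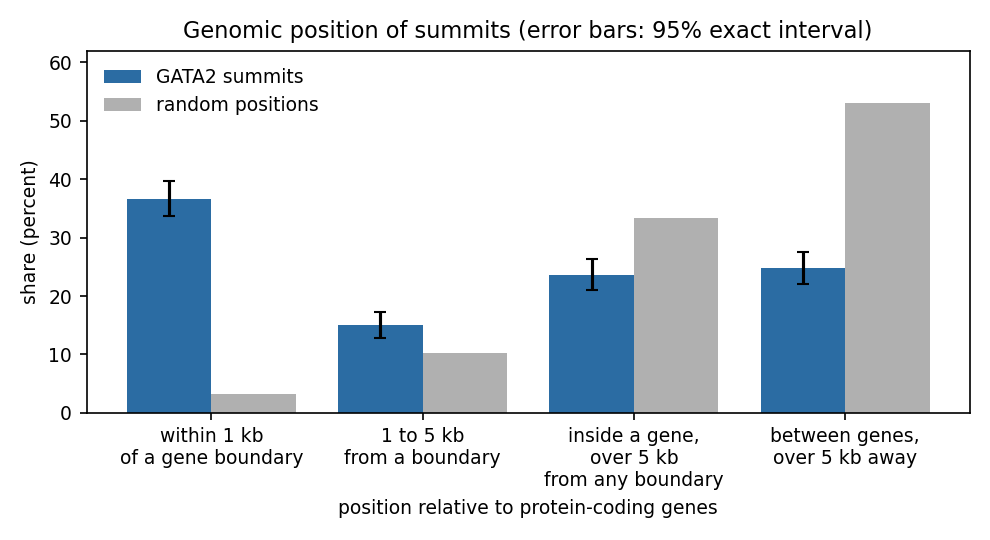
Share of 995 GATA2 summits (blue, with 95% exact binomial intervals) and of 9950 random positions on the same chromosomes (grey) in 4 classes of position relative to protein-coding genes, in percent. Summits exceed random positions within 1 kb of a boundary (36.7% against 3.26%) and fall below them in both classes over 5 kb away.

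Because the study concerns the exit from pluripotency, summits near pluripotency genes were counted first. Of 40 such genes, 8 were the nearest gene to a summit within 100 kb, against a mean of 1.91 in matched random sets (permutation p = 0.0014, adjusted p = 0.0168). They were led by Etv5 (15.2-fold). Prdm14, a regulator of both pluripotency and germ cell fate, had a summit 38.6 kb away (7.71-fold, −log10 q 8.91, chromosome 1, summit at 13074797). Esrrb, an orphan nuclear receptor gene of the naive pluripotency network, had one inside the gene (7.56-fold, −log10 q 8.12, chromosome 12, 86473759). Sall4, a zinc finger factor gene, also had one inside the gene (4.86-fold, −log10 q 3.37, chromosome 2, 168762760). The other members were Sox2 (4.50-fold, 41.1 kb away, with a weaker summit at 45.1 kb), Klf5 (4.07-fold, 26.9 kb), Tbx3 (4.07-fold, 82.1 kb) and Pou5f1, which encodes OCT4. The Pou5f1 summit, 2.1 kb outside the gene, had a fold of 3.08 on 6 fragments and a −log10 q of 0.30, short of a q of 0.05. Nanog had no assigned summit, and the nearest one lay 62.7 kb outside it, inside Slc2a3 (6.64-fold). Most of these summits lay far from gene ends. Only 1 of the 40 genes had a summit within 1 kb (random mean 0.69) and 3 within 10 kb (random mean 1.15, permutation test, adjusted p = 0.603), so the excess was not detectable near gene ends. With only summits of q at most 0.05, 7 genes had one against a random mean of 1.25 (permutation test, adjusted p = 0.0084). With summits of −log10 q 5 or more, 3 genes had one against a random mean of 0.338 (permutation test, adjusted p = 0.12). The list passed under 6 of 10 alternatives, over which the adjusted p ran from 0.000799 to 1. The random sets were matched on chromosome and distance, but not on open chromatin or GC content. Cutting of open chromatin in general could therefore not be told apart from GATA2 binding as the source of the excess.

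No gene of the meiosis list was the nearest gene to a summit within 100 kb. By the approximate rule of 3, the count of 0 of 49 genes allows a share of up to 6.12% under this nearest-gene rule. The limit does not cover genes missed for lack of depth or because another gene was nearer. The random sets had a mean of 1.94 genes and 95% of them held 0 to 5, so at this number of summits a shortfall could not be tested (permutation p = 0.259, adjusted p = 0.604, for the lowest count possible). Stra8, the retinoic acid-induced gatekeeper of meiotic entry, was 2636.3 kb from the nearest summit. Its partner gene Meiosin (Bhmg1 in the annotation) was 597.2 kb away, and Sycp3, a structural gene of the synaptonemal complex, 1680.8 kb away. Rec8, encoding the meiotic cohesin subunit, had a summit 14.0 kb outside it (7.0-fold, −log10 q 7.02) for which Irf9 was the nearer gene. Zglp1, a GATA-like zinc finger gene that acts in the oogenic fate, had one at 31.4 kb (4.50-fold) for which Icam4 was nearer. When each summit was assigned to every gene within 100 kb, 5 meiosis genes were reached, with 7.31 expected from all protein-coding genes (Fisher's exact test, adjusted p = 0.614). The germ cell genes Dazl, Ddx4 and Kit lay 1464.3, 872.9 and 1538.0 kb from the nearest summit.

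Among germ cell genes, 2 of 30 had a summit (random mean 1.51, adjusted p = 1 by permutation), and these were Prdm1 and Dppa3. They are the genes whose transgenes mark the sorted cells. Prdm1 carried 11 summits in 9 intervals over 82.3 kb of chromosome 10, with folds of 3.19 to 17.5. Dppa3, which encodes STELLA, carried 5 summits in 2 intervals over 1.84 kb of chromosome 6, with folds of 3.18 to 7.07. Within 100 kb of Prdm1, 11 summits were counted, as many as the maximum over all 21631 protein-coding genes on these chromosomes, whose median was 0. Dppa3 had 5, a number reached by 17 genes, with summits of the same interval counted separately. A control background counted as raised when it exceeded the genome-wide level by more than 1%, so a rise to 0.0812 was enough. The control background was above the genome-wide level at 13 of these 16 summits (81.3%, 95% exact interval 54.4% to 96.0%), against 28.3% of 968 other summits outside a ribosomal RNA region (Fisher's exact test, p = 2.05e-05). Neighbouring summits share a local background, so that p is too small. With 1 summit per interval the background was raised in 8 of 11 intervals against 28.4% of 932 others (Fisher's exact test, p = 0.00318), and all 11 come from only 2 loci. It reached 1.22 control fragments per position at Prdm1 and 3.0 at Dppa3, against 0.0608 across the genome. With each summit assigned to every gene within 100 kb, 6 of the 30 germ cell genes were reached, with 4.47 expected (Fisher's exact test, adjusted p = 0.614).

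**Figure D3:**
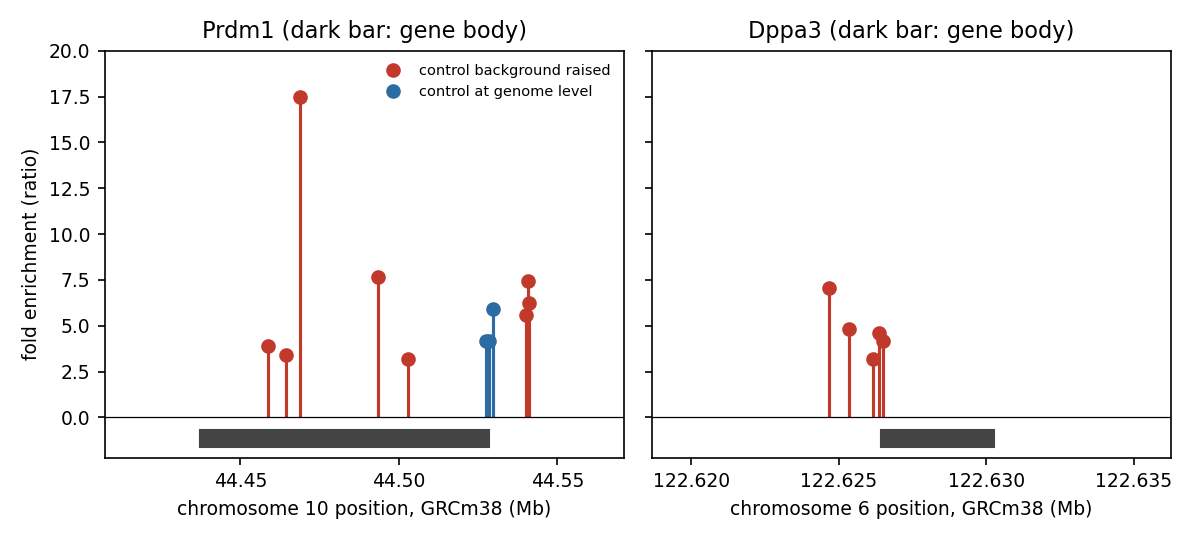
Fold enrichment (vertical axis, ratio) of the 11 summits nearest to Prdm1 on chromosome 10 and the 5 nearest to Dppa3 on chromosome 6 by GRCm38 position (horizontal axis, Mb). Each stem is 1 summit, red where the control background was above the genome-wide level and blue where it was not, and the dark bar is the gene body. Control was raised at 8 of 11 Prdm1 summits and at all 5 Dppa3 summits.

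Genes of the WNT pathway were nearest to summits more often than in the matched random sets, which again were not matched on open chromatin. Of 31 genes, 7 had a summit within 100 kb, against a random mean of 1.70 (permutation p = 0.0024, adjusted p = 0.0168). The strongest lay at Porcn, which encodes the acyltransferase needed for WNT secretion, 534 bp outside its boundary (12.0-fold, −log10 q 17.2, chromosome X, summit at 8207082). Tcf7l2, a nuclear effector gene, had one inside the gene (8.06-fold, −log10 q 8.91). Gsk3b, encoding a kinase of the beta-catenin destruction complex, had one 1 bp from a boundary (5.57-fold, −log10 q 3.37), and Znrf3, encoding a ligase that removes WNT receptors, one inside the gene (4.50-fold). The other 3 were Lgr5 (3.44-fold), Lef1 (3.44-fold) and Axin2 (3.34-fold), each with a −log10 q of 0.30 and thus short of a q of 0.05. With only summits of q at most 0.05, 4 genes had one against a random mean of 1.21 and the list did not pass (permutation test, adjusted p = 0.284), and over 10 alternatives the adjusted p ran from 0.000799 to 0.392.

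GATA family and cofactor genes numbered 4 of 15 (random mean 0.74, permutation p = 0.0124, adjusted p = 0.0579), which missed the threshold after adjustment. Zfpm1, encoding the GATA cofactor FOG1, had 5 summits over 13 kb at and inside the gene, with folds of 3.40 to 5.94. The others were Lmo4 (4.50-fold), Gatad2a (3.79-fold, 64 bp from a boundary) and Gata2 itself, with a summit 4.1 kb outside the gene (chromosome 6, 88189799, 3.44-fold on 7 fragments, −log10 q 0.30). BMP and TGF-beta genes numbered 6 of 35 (random mean 2.07, permutation p = 0.0282, adjusted p = 0.0987). Id3, a BMP target gene encoding an inhibitor of E proteins, had 4 summits within 2.4 kb of its ends, the strongest at 11.3-fold (chromosome 4, 136147011). Smad3 (8.09-fold), Smad5 (4.28-fold), Bmp4 (3.66-fold), Msx2 (3.08-fold) and Smad6 (3.02-fold) had 1 summit each, and of these 5 only the Smad3 summit had a q under 0.05 (−log10 q 7.57). Retinoic acid genes numbered 2 of 21 (random mean 1.14, adjusted p = 0.986 by permutation), Nrip1 (5.57-fold, inside the gene) and Rxra (3.44-fold).

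None of the 3 lists of markers of other cells of the fetal ovary passed the test. The somatic gonad list had 3 of 25 genes near a summit (random mean 1.40, adjusted p = 0.641 by permutation), Sox9 (5.57-fold, 83.0 kb away), Lgr5, which is also in the WNT list, and Irx5 (2.86-fold). The blood list had 1 of 31 (random mean 1.55, permutation test, adjusted p = 1), Zfpm1, which is also in the GATA list. The endothelium list had 0 of 20 (random mean 0.80, permutation test, adjusted p = 1), which by the rule of 3 allows a share of up to 15% under the nearest-gene rule. Oocyte genes had 0 of 20 (random mean 0.89, permutation test, adjusted p = 1), with the same limit, and genes of chromatin repression and DNA methylation 0 of 32 (random mean 1.46, permutation test, adjusted p = 0.763), with a limit of 9.38%. The mitotic cell cycle list had 1 of 30 (random mean 1.19, permutation test, adjusted p = 1), Cdkn1a (3.44-fold). The ribosomal protein list had 3 of 33 (random mean 0.80, permutation test, adjusted p = 0.243), Rpl22 with 3 summits (5.93-fold at most), Rpl11 (4.15-fold) and Rpl13 (3.08-fold). With random means this low, a list with fewer genes than chance could not pass the test.

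**Figure D4:**
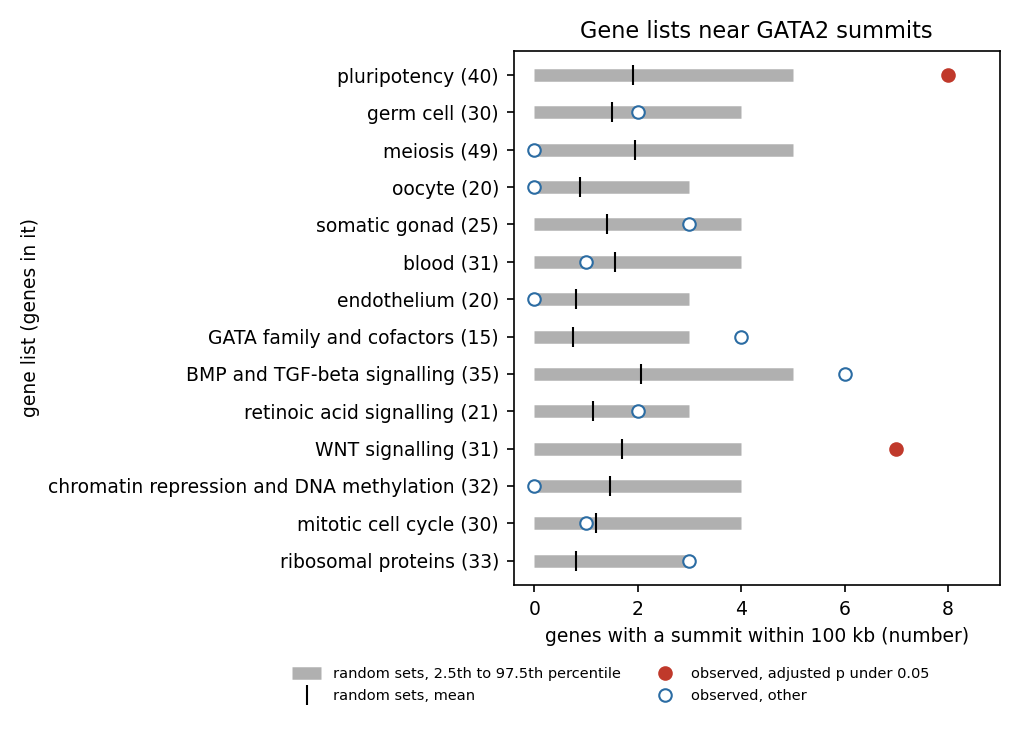
Number of genes with an assigned summit within 100 kb (horizontal axis) in each of 14 gene lists (vertical axis, with the number of genes in the list). Points are observed numbers, ticks the mean and grey bars the central 95% of 10000 matched random summit sets. Filled red points mark the pluripotency list (8 genes) and the WNT list (7 genes), whose adjusted p was under 0.05.

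The other genes with the most summits were Esp38 (11), Dnah2 (4) and Id3 (4). The 11 summits assigned to Esp38 lay 102.0 to 107.1 kb from it, in 2 intervals of chromosome 17 that overlap both ends of the 18S ribosomal RNA pseudogene Rn18s-rs5 (39846354 to 39848202), with 0 summits inside it. Their folds were 2.12 to 4.37 and 41 to 87 GATA2 fragments lay at each summit, while the control background there was 3.04 to 13 fragments per position. The 4 Dnah2 summits, all inside the gene, spanned 34.2 kb of chromosome 11, with folds of 4.07 to 12.0.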

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

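The settings with 1 summit per interval, a q of at most 0.05, the loci left out and every gene within 100 kb were chosen after seeing the data. The concentration of summits at gene boundaries kept its direction and stayed past the threshold under all 9 alternatives, with 27.1% to 45.7% of summits at boundaries and a largest p of 1.25e-26. Its size fell from 11.3 times the random share to 5.16 times with a 3 kb window (45.7% against 8.85%) and to 6.49 times with all annotated genes (42.1% against 6.49%), both of which cover more of the genome, and lay between 9.51 and 11.4 times in the other 7. The number of summits fell from 995 to 177 at a −log10 q of 5 or more and to 497 when only those of higher fold were kept. Of the 140 list results under 10 alternatives each, 127 kept their side of the threshold, 8 lost it and 5 gained it, and 0 turned direction past the threshold. Most of these results belong to lists that did not pass as reported. The pluripotency list and the WNT list each kept their call under 6 of 10 alternatives. The number of lists past the threshold, 2 as reported, was 0 at a −log10 q of 5 or more, 0 among those 497, 0 within 1 kb, 1 at a q of at most 0.05 (the pluripotency list) and 4 with Fisher's exact test. The pluripotency list, 8 genes as reported, lost its call with 3 genes against a random mean of 0.338 at a −log10 q of 5 or more (adjusted p = 0.12), 5 against 0.956 among those 497 (0.0896), 3 against 1.15 within 10 kb (0.603) and 1 against 0.691 within 1 kb (adjusted p = 1), by permutation tests. The WNT list, 7 genes as reported, lost it with 2 genes against 0.333 at a −log10 q of 5 or more (adjusted p = 0.392), 4 against 0.931 among those 497 (0.169), 4 against 1.21 at a q of at most 0.05 (0.284) and 3 against 0.472 within 1 kb (0.214), by permutation tests. The random means as reported were 1.91 and 1.70, and stricter thresholds and shorter distances leave fewer summits to test. The GATA list gained a call with 4 genes at 1 summit per interval (adjusted p = 0.0327), without the Prdm1, Dppa3 and ribosomal RNA loci (0.0411), within 10 kb (0.0252) and with Fisher's exact test (0.00649), with adjusted p of up to 1 under others. The last also called the BMP and TGF-beta list with 6 genes (0.00649), and it does not allow for the space around genes. For Dppa3, widening the window to 250 kb moved the share of genes with fewer summits from 99.92% to 99.61%. No paired analysis was possible because the 1 pooled list carries no values per replicate, and for the same reason no replicate could be left out. Alternatives that need the genome sequence (motif, 6-mer and motif panel tests, GC matching, repeats, summits with a GATA motif alone) were not run. With a median of 9 fragments at a summit, the depth limits what can be said of any weak summit and of genes without one.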

Other observations

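The tests of FGF-ERK and imprinted genes, of the X chromosome and of the control background and endogenous binding at the transgene loci were chosen after the summits had been seen. A few genes that respond to FGF and ERK signalling were noticed at strong summits and led to a list of such genes. Besides Etv5 (15.2-fold), Egr2 (10.9-fold, 75.5 kb away), Nf1, which encodes a negative regulator of RAS (10.9-fold, 12.4 kb), Csrnp1 (10.6-fold, inside the gene) and Spred2, which encodes an inhibitor of RAS-ERK signalling (10.2-fold, 9.8 kb), were nearest to summits. The phosphatase genes Dusp6 (4.86-fold), Dusp9 (4.50-fold) and Dusp1 (3.02-fold) and the immediate early gene Fos (4.50-fold) also had summits. In all, 9 of 28 such genes had one within 100 kb, but the list was written after 6 of them had been noticed. Among the 22 members not seen beforehand, 3 had a summit, against a random mean of 1.09 (permutation p = 0.182), namely Dusp6, Fos and Dusp1, so an excess for the group, a hypothesis, was not shown. Imprinted genes gave 5 of 30, namely Slc38a4 (9.49-fold, 72.4 kb away), Peg3 with 3 summits (5.86-fold), Igf2 (4.42-fold), Usp29 (3.37-fold) and Magel2 (3.08-fold). Without Peg3, which had been noticed first, 4 of 29 had a summit against a random mean of 1.54 (permutation p = 0.134), and that excess was not shown either. Usp29 stayed among the 29, although its summit (6732384) neighbours that of Peg3 (6728641) on chromosome 7. The 29 genes were thus not fully independent of what had been noticed.

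The X chromosome held 17 of 995 summits (1.71%, 95% exact interval 0.998% to 2.72%), against 4.47% of the protein-coding genes (exact binomial test, p = 3.37e-06). That is 1.76 summits per 100 genes, below the 3.22 of chromosome 15, the lowest autosome. Porcn carried the strongest of them, 12.0-fold. The binomial test counted summits of the same interval separately and made no allowance for how well reads map on the X chromosome.

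The first pattern to weigh is the cluster of summits at Prdm1 and Dppa3, the genes of the reporter transgenes. Extra copies of these loci in the sorted cells would add fragments there, and a prediction written before these summits were counted was met: 99.92% of protein-coding genes had fewer summits within 100 kb than Dppa3, and more had fewer than Prdm1. Summits of the same interval were counted separately. The 5 at Dppa3 lie in only 2 intervals and the 11 at Prdm1 in 9, and the ranking was not repeated by interval. Extra copies would raise the control as well, and its background was above the genome-wide level at 81.3% of these summits against 28.3% elsewhere (72.7% against 28.4% with 1 summit per interval). Transgene copies could thus be a source of part of the signal. At the Prdm1 summits 44527406, 44528561 and 44529662, however, the control background was at the genome-wide level (0.0608). The control background was raised at the next summits on either side, 44502906 and 44539990. The summits at the genome-wide level lie close together, and that level stands for few control fragments. Whether the raised control extended across the whole locus could therefore not be decided. GATA2 binding at the endogenous genes remains open for all 16 summits, since neither copy number nor transgene ends are given and cells without the transgenes were not analysed here.

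The second pattern is the 321 summits with a q above 0.05, for which noise placed by chance is a candidate explanation. It predicts the random share of 3.26% at gene boundaries. The observed share was 42.7% with a lower bound of 37.2%, which argues against chance placement as the cause of this set as a whole. It does not show that GATA2, rather than open chromatin, placed them.

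The third pattern is the concentration at gene boundaries, which might reflect cutting of open promoters in general, a known property of Tn5-based assays, instead of a set chosen by GATA2. Ribosomal protein genes, whose promoters are open in dividing cells, served as a control fixed in advance. They had 1 gene with a summit within 1 kb against a random mean of 0.53 (permutation p = 0.836), too few to decide. General promoter cutting and GATA2 binding cannot be told apart for these summits, since the motif was not tested and no antibody against another protein was analysed here.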
